A study of Mus musculus with 6 samples.

How the data were processed

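RNA was taken from the livers of 3 Usp28 knockout samples and 3 wild-type samples, all from mice on a methionine-choline deficient diet. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with a NEBNext Ultra RNA kit. The labels do not say whether the 3 samples of a group came from 3 animals, so p-values measure the spread between these samples, part of which may be technical. The sex and the feeding of the mice before collection are not in the labels. Per the submitters' processing notes, fastp 0.18.0, HISAT2, StringTie 1.3.1 and RSEM were used. Their order and roles, the genome build, the annotation, the use of strand and the test behind the authors' p-values are not given in the sources used here.

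The authors deposited whole-number read counts per gene and sample, and FPKM per gene and sample (fragments scaled to transcript length and library depth), per the file headers. Beside these stood the authors' mean FPKM of each group, the log2 fold change of the KO mean over the WT mean, a p-value and an FDR. A mean of 0 was replaced by 0.001 in the authors' means, which applied to 2 genes in KO. The 389 genes of the table are a selection: their smallest absolute log2 fold change in the authors' deposited table was 1.004 and their largest deposited FDR 0.0494. Dividing the authors' FDR by their p-values for the 19 leading genes gave the number of genes they tested as 16194 to 16202, with 16198 as its middle. By the same relation the last gene of the table had rank 823, so about 434 genes passed the authors' FDR without entering the table. All values of fold change, SE and adjusted p in the text were computed from the deposited counts, not taken from the authors' columns. Gene symbols and IDs are those of the table. 388 of its 389 IDs matched the GENCODE M21 annotation of GRCm38, from which positions were taken, and 1 symbol differed. Usp28 (chromosome 9, 48985375 to 49042517) and Pparg (chromosome 6, 115360951 to 115490399) had no row, so the planned test of each was not made.

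A sum over selected genes is not a library's depth. Depth was therefore recovered as the median of count divided by FPKM and transcript length, over 38 to 51 genes per library that have a single annotated transcript, at least 50 counts and at least 1 FPKM. It came to between 20350000 and 24160000 reads, and the ratios between libraries were checked over 237 genes. Counts of the listed genes summed to 1781233, 2129264 and 1108937 in WT replicates 1, 2 and 3, and to 786173, 831662 and 814194 in KO replicates 1, 2 and 3. Replicates of a group differed by far more than counting noise (chi-square per degree of freedom from 46.1 to 1018), so none was treated as a duplicate.

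Counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test, with the recovered depth as library size, no further scaling and no filter, and Benjamini-Hochberg adjustment over the 389 listed genes. The median biological coefficient of variation was 0.347. The design written before the data were examined named this test for a count table of all genes and an unfiltered test for a table of selected genes. The table held counts of selected genes, so the 2 were combined, and scaling by TMM, which assumes that most genes are unchanged, was kept as an alternative. On counts simulated for the 389 genes, edgeR called 30 of 100 genes given an absolute log2 change of 1, 91 of 100 given one of 2, and 3 of 189 left unchanged. limma 3.58.1 called 28, 91 and 3. In 363 of the listed genes the 3 KO values did not overlap the 3 WT values, where chance gives 10% of genes, but the genes were selected on this comparison. FPKM values are given as mean ± SD per group. The SE beside an edgeR fold change was derived from the test, as the absolute log2 fold change divided by the square root of its quasi-likelihood F statistic.

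Gene groups were 39 lists written from textbook knowledge before the data were examined, and 13 of them had no listed member. For the 9 lists with at least 5 listed members, members higher and lower in KO were compared with those of the other listed genes by a two-sided Fisher's exact test, adjusted over the 9 lists. This compares directions within a selected table and is not an enrichment against all genes. A one-sided exact hypergeometric test of how many members were listed, adjusted over the 39 lists, was added after the data were seen. It takes 16198 genes as background and assumes that every annotated member of a list was among them, which was not checked. Both tests count the genes of a list as independent, which genes regulated together are not. Their p-values therefore do not measure the spread between samples. Set tests on a ranking of all genes (camera and fry) were not run, because they need a table of all genes.

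Genes were named by a rule written before the data were examined. It takes up to 3 members past the threshold with the largest absolute log2 fold change from each list, in order of how many members passed and up to 24 genes over all lists. To these it adds the 5 highest and 5 lowest genes that have at least 1 FPKM in the higher group and no overlap between groups, passing over predicted genes. The rule gave 32 genes, 1 of which is not reported here. Other genes are named to identify a count, and were chosen after their values were seen. The alternatives were limma on log2(FPKM + 0.1) and with pseudocounts of 1 and 0.01, limma without trend, a mean FPKM of at least 1, filterByExpr, median centring, TMM and relative log expression factors, DESeq2 1.42.0, replicate number as a block, a minimum fold change, adjustment over more genes, and leaving out each library in turn. Fold changes from limma are on the log2(FPKM + pseudocount) scale, which understates changes of low genes. Lists and figures were computed with Python 3.11.15, scipy 1.17.1, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.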

Results

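Liver RNA was sequenced from mice lacking Usp28 in the whole body (KO, 3 samples) and from wild-type mice (WT, 3 samples). Usp28 encodes a deubiquitinase, an enzyme that removes ubiquitin from other proteins. All 6 samples came from mice that ate a methionine-choline deficient diet, a feeding model of steatohepatitis, for 4 weeks from the age of 8 weeks. A group on a control diet was not analysed here. Sequencing depth, recovered from the counts and FPKM values of the same genes, was 20370000, 24160000 and 20350000 reads in WT replicates 1, 2 and 3, and 20860000, 22130000 and 21820000 in KO replicates 1, 2 and 3. The table analysed here held 389 genes, called the listed genes below, which the authors had already selected for a difference between KO and WT. These genes took 8.75%, 8.81% and 5.45% of the reads of WT replicates 1, 2 and 3, and 3.77%, 3.76% and 3.73% of those of KO replicates 1, 2 and 3. Positions are given for the mouse build GRCm38.

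The comparison of KO with WT liver addressed which transcripts differ when Usp28 is absent under this diet, in a study whose title names PPARγ expression as dependent on USP28. In KO liver, all 19 listed genes of the group of fatty acid oxidation and PPARA targets were lower, and all 5 listed genes of cholesterol synthesis and all 5 of endoplasmic reticulum stress were higher. These 3 groups passed the test of direction against the other listed genes. In the cholesterol and stress groups WT replicate 3 lay close to 1 KO library. Relative to the KO mean on the log2 scale, the median cholesterol gene was at -0.62 in WT replicate 3 and -0.52 in KO replicate 3. The median stress gene was at -0.58 in WT replicate 3 and -0.51 in KO replicate 1. Single genes were less firm: 4 of the 5 cholesterol genes passed, and 1 without KO replicate 1 or 2, while 2 of the 5 stress genes passed without WT replicate 1, KO replicate 2 or KO replicate 3. All 6 listed lipid droplet genes and 5 of 6 listed acute phase genes were lower, and 8 of 11 listed lipogenesis genes and 5 of 6 listed glucose handling genes were higher, but these directions did not pass. Nor did that of the 6 listed macrophage markers, which were lower by a median log2 fold change of -1.67, or -0.89 without WT replicate 3. For the lipid droplet and macrophage groups the test could not pass. Most listed genes were lower, so 6 of 6 lower gives an unadjusted p of 0.0852 (two-sided Fisher's exact test). Of the 389 listed genes, 156 were higher and 233 lower in KO. In edgeR's quasi-likelihood test, 388 of them passed an adjusted p of 0.05 over the listed genes (155 higher, 233 lower, so 40.0% higher). Because the genes were selected on this comparison, that count follows from the selection. The same p-values adjusted over the 16198 genes that the authors' p-values and FDR imply left 5 genes, all lower in KO: Cidec, Mt2, Il1rn, Cdc42ep5 and Cgref1. DESeq2's p-values adjusted over the same number left 153 genes, 50 higher and 103 lower. Both adjustments ranked genes without a row as unchanged, although about 434 of them passed the authors' FDR. With these p-values both counts are therefore lower limits. Cdc42ep5 and Cgref1 were named after their values were seen. Scaling that assumes most listed genes to be unchanged gave 156 higher and 80 lower genes with relative log expression factors (66.1% higher), and 156 higher and 83 lower with DESeq2's own factors (65.3% higher). No listed gene changed direction when any 1 library was left out, which the 363 genes without overlap between groups could hardly do. The scalings could not turn a direction, since they moved the median gene by at most 0.65 on the log2 scale and the genes had been selected for an absolute log2 fold change of at least 1.004. Neither Usp28 nor Pparg had a row among the genes analysed here, so the genotype labels were not checked against the targeted gene, and no level of either gene is reported. If they were among the genes the authors tested, neither met the selection on fold change and FDR that gave the listed genes. A lower Pparg transcript level can therefore not be read from the lower PPARG targets.

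In the group of PPARG targets and lipid droplet genes, all 6 listed members (Cidec, Plin2, Pnpla2, Cd36, Fitm2 and Hilpda) were lower in KO. Cidec (ENSMUSG00000030278, chromosome 6, 113424634 to 113435760), which encodes a lipid droplet protein that promotes droplet growth, was 32.8-fold lower. It stood at 124 ± 20.2 FPKM in WT and 3.66 ± 0.638 in KO (mean ± SD, n = 3 each), a log2 fold change of -5.04 ± 0.34 (SE, edgeR adjusted p = 1.15e-05). Plin2 (ENSMUSG00000028494, chromosome 4, 86648386 to 86670060), which encodes a coat protein of lipid droplets, stood at 945 ± 158 FPKM in WT and 284 ± 70.6 in KO (SD, n = 3 each). Its log2 fold change was -1.71 ± 0.36 (SE, edgeR adjusted p = 0.00462). Pnpla2, which encodes the lipase that starts triglyceride breakdown, stood at 153 ± 53.3 FPKM in WT and 42.0 ± 5.39 in KO (SD, n = 3 each), a log2 fold change of -1.82 ± 0.34 (SE, edgeR adjusted p = 0.00356). The 6 listed members compare with 0.84 expected by chance among 35 annotated members (one-sided exact hypergeometric test, adjusted p = 0.000925). Their shared direction did not pass the test against the other listed genes (two-sided Fisher's exact test, p = 0.0852, adjusted p = 0.110). With 233 of the 389 listed genes lower, 6 of 6 lower could not pass, so that test does not decide. Of the 6 members, 5 passed without WT replicate 1 or without any 1 KO replicate.

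The group of fatty acid oxidation genes and PPARA targets had 19 listed members of 44, against 1.06 expected (one-sided exact hypergeometric test, adjusted p = 3.48e-18), and all 19 were lower in KO (two-sided Fisher's exact test of direction, adjusted p = 0.000457). They included Ppara and Ppargc1a, which encode regulators of this pathway, and the enzyme gene Cpt1a. Ehhadh (ENSMUSG00000022853, chromosome 16, 21761287 to 21787807), which encodes a peroxisomal oxidation enzyme, stood at 762 ± 535 FPKM in WT and 102 ± 15.4 in KO (SD, n = 3 each), a log2 fold change of -2.90 ± 0.63 (SE, edgeR adjusted p = 0.00543). Vnn1 (ENSMUSG00000037440, chromosome 10, 23894688 to 23905343), which encodes pantetheinase, stood at 60.2 ± 27.4 FPKM in WT and 13.4 ± 1.87 in KO (SD, n = 3 each, log2 fold change -2.17 ± 0.41, SE, edgeR adjusted p = 0.00346). Acot1, which encodes an acyl-CoA thioesterase, had a log2 fold change of -2.73 ± 0.56 (SE, edgeR adjusted p = 0.00462), but its reads can be shared with the closely related Acot2. WT replicate 3 lay between the groups: the median member of this group was 1.93 and 1.67 above the KO mean on the log2 scale in WT replicates 1 and 2, and 0.51 above it in WT replicate 3. Between 13 (without KO replicate 1 or 2) and 19 (without WT replicate 3) members passed when 1 library was left out.

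In the de novo lipogenesis group, 11 of 28 members were listed, against 0.67 expected (one-sided exact hypergeometric test, adjusted p = 3.87e-10). 8 were higher in KO (among them Srebf1, Mlxipl, Acly, Elovl6, Pklr and Mid1ip1) and 3 were lower (Acacb, Elovl5 and Fads2), a split that did not pass the test of direction (two-sided Fisher's exact test, adjusted p = 0.0702). Pklr (ENSMUSG00000041237, chromosome 3, 89136142 to 89146784), which encodes liver pyruvate kinase, stood at 75.7 ± 39.2 FPKM in WT and 260 ± 32.3 in KO (SD, n = 3 each, log2 fold change 2.04 ± 0.48, SE, edgeR adjusted p = 0.00689). Mid1ip1, whose product activates acetyl-CoA carboxylase, stood at 6.87 ± 3.61 FPKM in WT and 22.0 ± 4.17 in KO (SD, n = 3 each), a log2 fold change of 1.95 ± 0.45 (SE, edgeR adjusted p = 0.00632). Without WT replicate 3 the log2 fold change of Mid1ip1 was 2.64, and the median of the 11 members went from 1.34 to 1.95. Without WT replicate 2, 7 of the 11 passed.

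Pklr also belongs to the group of gluconeogenesis and glucose handling, of which 6 of 27 members were listed against 0.65 expected (one-sided exact hypergeometric test, adjusted p = 0.000347). 5 were higher in KO, among them Pklr, Ppp1r3b and Khk, and Gys2, which encodes liver glycogen synthase, was lower (two-sided Fisher's exact test of direction, adjusted p = 0.0724). Ppp1r3b, which encodes a phosphatase subunit that binds glycogen, had a log2 fold change of 1.61 ± 0.30 (SE, edgeR adjusted p = 0.00335). Without WT replicate 1, 4 of the 6 passed and Khk did not (log2 fold change 0.88, edgeR adjusted p = 0.0530), and 5 passed without any 1 KO replicate.

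In the group of cholesterol synthesis and uptake, 5 of 25 members were listed against 0.60 expected (one-sided exact hypergeometric test, adjusted p = 0.00136), and all 5 were higher in KO (two-sided Fisher's exact test of direction, adjusted p = 0.0299). Mvd, Msmo1, Fdft1 and Mvk passed, and Cyp51, named after its values were seen, was the listed gene that did not (log2 fold change 1.20 ± 0.56, SE, edgeR adjusted p = 0.0565, and 2.02 without WT replicate 3, where it passed). Mvd, which encodes mevalonate diphosphate decarboxylase, had a log2 fold change of 1.52 ± 0.60 (SE, edgeR adjusted p = 0.0307), and Msmo1, which encodes a sterol oxidase, one of 1.41 ± 0.52 (SE, edgeR adjusted p = 0.0232). These calls were fragile. Mvd did not pass without WT replicate 1, KO replicate 1 or KO replicate 2 (edgeR adjusted p = 0.0514, 0.0666 and 0.118), and had a log2 fold change of 2.27 without WT replicate 3. Msmo1 did not pass without WT replicate 2, KO replicate 1 or KO replicate 2 (edgeR adjusted p = 0.0513, 0.0803 and 0.0708). The number of members that passed was 2 without WT replicate 2, 1 without KO replicate 1, 1 without KO replicate 2 and 5 without WT replicate 3.

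In the group of bile acid synthesis and transport, 6 of 24 members were listed against 0.58 expected (one-sided exact hypergeometric test, adjusted p = 0.000224). Cyp7a1, Cyp2c70, Abcb11 and Slc51b were higher in KO, and Nr0b2 and Slco1a4 were lower (two-sided Fisher's exact test of direction, adjusted p = 0.252). Cyp7a1 (ENSMUSG00000028240, chromosome 4, 6265612 to 6275633), which encodes the rate-limiting enzyme of bile acid synthesis, stood at 9.13 ± 3.68 FPKM in WT and 23.7 ± 8.51 in KO (SD, n = 3 each), a log2 fold change of 1.38 ± 0.40 (SE, edgeR adjusted p = 0.0115). Cyp2c70, which encodes the enzyme that makes muricholic acids in mice, stood at 64.2 ± 52.1 FPKM in WT and 237 ± 28.9 in KO (SD, n = 3 each, log2 fold change 1.88 ± 0.52, SE, edgeR adjusted p = 0.00987), and at a log2 fold change of 2.80 without WT replicate 3. Slc51b, which encodes a subunit of a bile acid exporter, had a log2 fold change of 1.65 ± 0.59 (SE, edgeR adjusted p = 0.0210). It was 2.39 without WT replicate 3, and did not pass without KO replicate 2 (log2 fold change 1.39; edgeR adjusted p = 0.0895), where 3 of the 6 members passed.

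The group of endoplasmic reticulum stress and integrated stress response genes had 5 listed members of 33, against 0.79 expected (one-sided exact hypergeometric test, adjusted p = 0.00460). All 5 (Atf4, Ddit3, Chac1, Dnajb9 and Herpud1) were higher in KO (two-sided Fisher's exact test of direction, adjusted p = 0.0299). Chac1 (ENSMUSG00000027313, chromosome 2, 119351229 to 119354381), which encodes a glutathione-degrading enzyme, stood at 1.0 ± 0.797 FPKM in WT and 12.2 ± 8.35 in KO (SD, n = 3 each), a log2 fold change of 3.61 ± 0.75 (SE, edgeR adjusted p = 0.00462), and 4.50 without WT replicate 3. Dnajb9, which encodes a chaperone of the endoplasmic reticulum, had a log2 fold change of 1.31 ± 0.43 (SE, edgeR adjusted p = 0.0168) and did not pass without KO replicate 1 (edgeR adjusted p = 0.0530). Ddit3, which encodes the transcription factor CHOP, had a log2 fold change of 1.20 ± 0.48 (SE, edgeR adjusted p = 0.0314). It did not pass without WT replicate 1, WT replicate 2, KO replicate 2 or KO replicate 3 (edgeR adjusted p = 0.0907, 0.0982, 0.0661 and 0.160), and was 1.85 without WT replicate 3. Of the 5 members, 2 passed without WT replicate 1, KO replicate 2 or KO replicate 3, and 3 without WT replicate 2 or KO replicate 1.

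**Figure D1:**
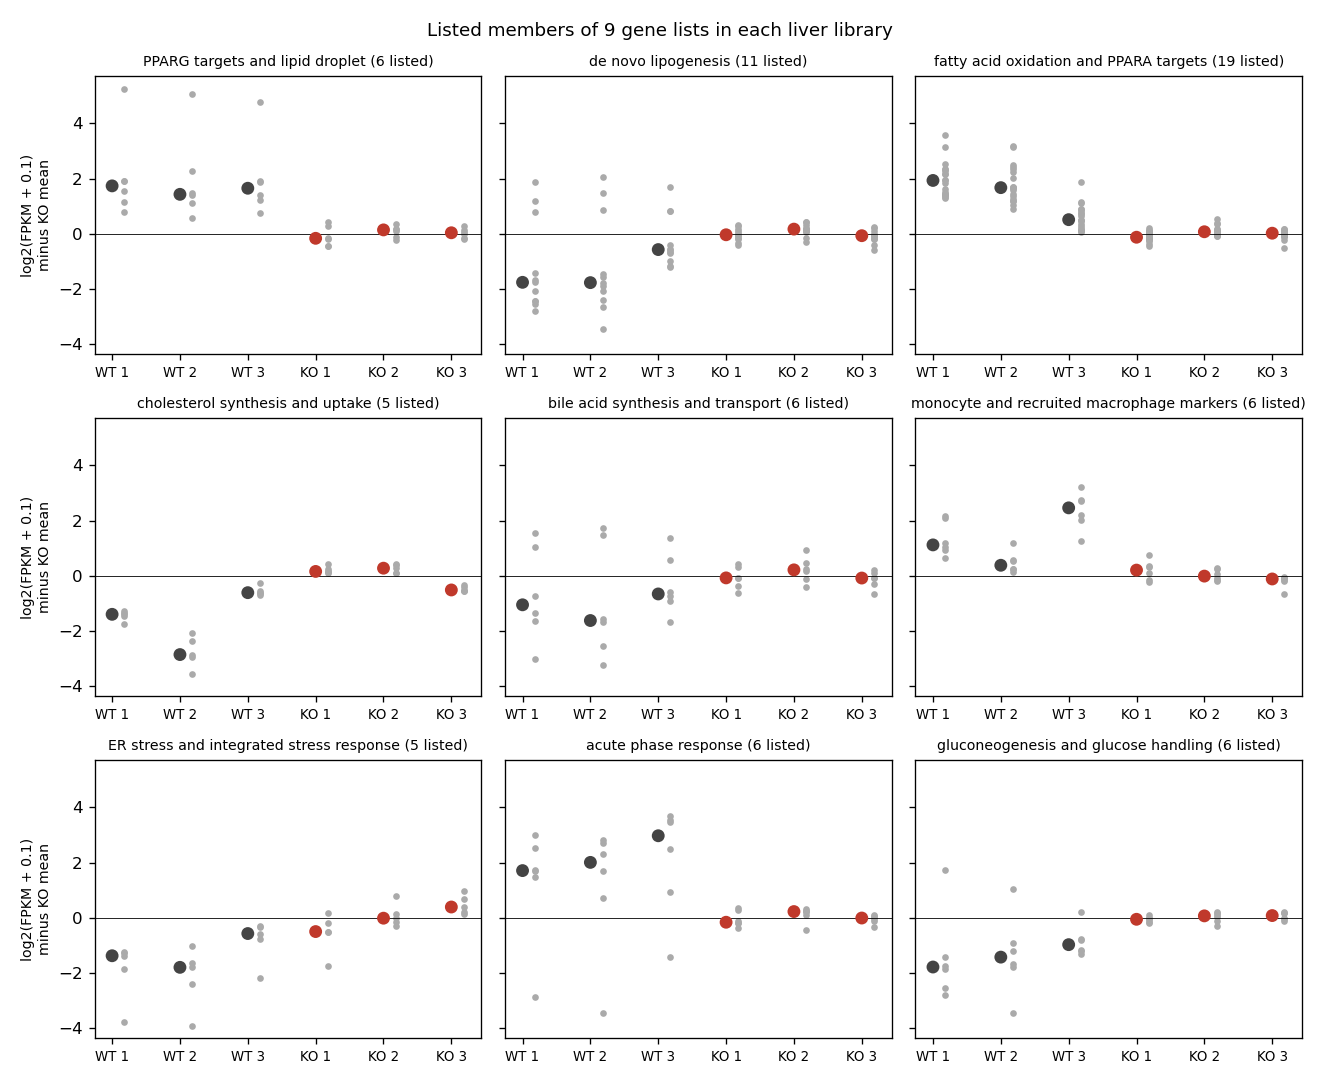
Each panel shows the listed members of 1 gene group as log2(FPKM + 0.1) minus the mean of the 3 KO libraries, with grey points for genes and a large point for the median of each library (black WT, red KO). In the oxidation panel the WT medians were 1.93, 1.67 and 0.51, with WT replicate 3 nearest the KO libraries, and in the macrophage panel WT replicate 3 stood highest at 2.46.

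In the group of monocyte and recruited macrophage markers, 6 of 32 members were listed against 0.77 expected (one-sided exact hypergeometric test, adjusted p = 0.000641), and all 6 (Mmp12, Gpnmb, Lgals3, Cd14, Itgam and Itgax) were lower in KO (two-sided Fisher's exact test of direction, p = 0.0852, adjusted p = 0.110). With most listed genes lower, 6 of 6 lower could not pass this test, which therefore does not decide. Mmp12, which encodes macrophage elastase, stood at 28.0 ± 23.8 FPKM in WT and 5.66 ± 0.488 in KO (SD, n = 3 each), a log2 fold change of -2.32 ± 0.61 (SE, edgeR adjusted p = 0.00908). Gpnmb, a gene of lipid-associated macrophages, had a log2 fold change of -1.94 ± 0.44 (SE, edgeR adjusted p = 0.00632). Lgals3, which encodes galectin-3, had a log2 fold change of -1.69 ± 0.56 (SE, edgeR adjusted p = 0.0163). Much of this difference lay in WT replicate 3. The median member stood 1.12, 0.38 and 2.46 above the KO mean on the log2 scale in WT replicates 1, 2 and 3. Without WT replicate 3 the median log2 fold change of the group went from -1.67 to -0.89, that of Mmp12 to -1.45, and 4 of 6 members passed. Lgals3 (-0.70; edgeR adjusted p = 0.0642) and Cd14 (-0.43; edgeR adjusted p = 0.156) then did not pass. Without KO replicate 2, 3 members passed, and Lgals3 did not (edgeR adjusted p = 0.0657). No member of the Kupffer cell group was listed.

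In the acute phase group, 6 of 31 members were listed against 0.74 expected (one-sided exact hypergeometric test, adjusted p = 0.000637). Mt2, Mt1, Il1rn, Lcn2 and Socs3 were lower in KO and Hamp2 was higher (two-sided Fisher's exact test of direction, adjusted p = 0.409). Il1rn (ENSMUSG00000026981, chromosome 2, 24336853 to 24351494), which encodes the antagonist of the interleukin-1 receptor, stood at 21.0 ± 5.69 FPKM in WT and 2.40 ± 0.419 in KO (SD, n = 3 each), a log2 fold change of -2.94 ± 0.35 (SE, edgeR adjusted p = 0.000761). Mt2 (ENSMUSG00000031762, chromosome 8, 94172664 to 94173568), which encodes a metallothionein, stood at 244 ± 107 FPKM in WT and 28.8 ± 4.44 in KO (SD, n = 3 each, log2 fold change -3.09 ± 0.38, SE, edgeR adjusted p = 0.000761). Lcn2, which encodes lipocalin 2 and is also in the neutrophil group and the group of inflammatory cytokines and chemokines, had a log2 fold change of -2.54 ± 0.54 (SE, edgeR adjusted p = 0.00520), and -1.58 without WT replicate 3. Without WT replicate 1, 5 of the 6 members passed. Lcn2 was the 1 listed member of the 16 neutrophil markers and of the 48 cytokine and chemokine genes.

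In the group of fibrosis and extracellular matrix, 4 of 49 members were listed against 1.18 expected, which did not pass (one-sided exact hypergeometric test, adjusted p = 0.0891). 3 were lower in KO, among them Timp1 and Mmp12, and Col5a3, which encodes a collagen chain, was higher. Timp1, the gene of an inhibitor of matrix-degrading enzymes, had a log2 fold change of -3.43 ± 1.10 (SE, edgeR adjusted p = 0.0152). It did not pass without WT replicate 3 (-1.60; edgeR adjusted p = 0.0674) or KO replicate 1 (-3.11; edgeR adjusted p = 0.0526), and was -4.54 without KO replicate 2. Col5a3 did not pass without WT replicate 1 or KO replicate 2 (edgeR adjusted p = 0.0552 for both). No member of the stellate cell and myofibroblast group was listed.

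**Figure D2:**
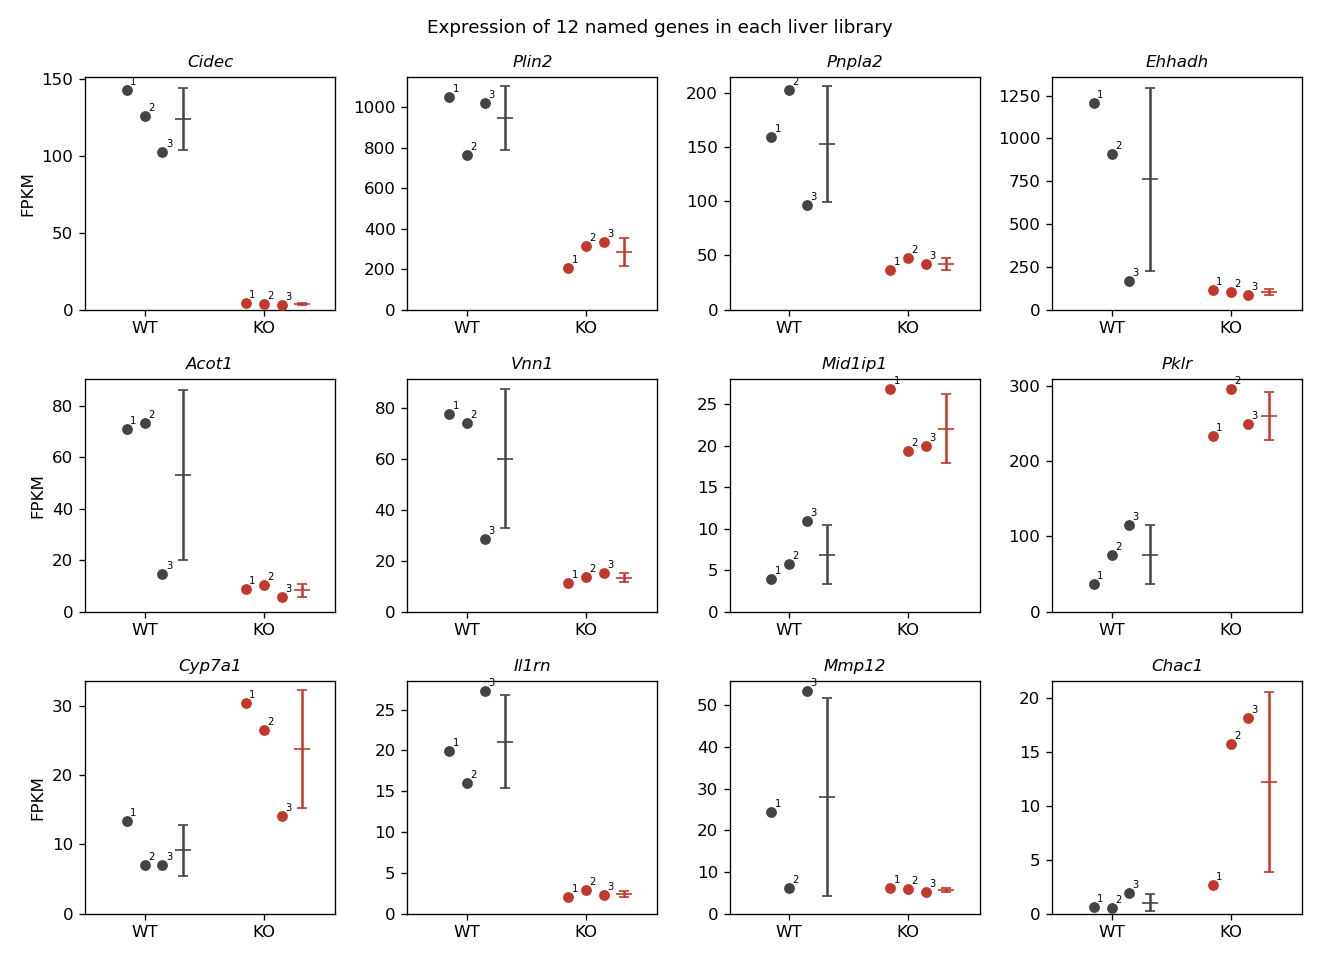
FPKM of 12 named genes in the 3 WT libraries (black) and the 3 KO libraries (red), on linear axes from 0, with replicate numbers beside the points and bars for mean ± SD (n = 3 each). Cidec stood at 124 ± 20.2 FPKM in WT and 3.66 ± 0.638 in KO, whereas in Ehhadh and Acot1 WT replicate 3 lay near the KO libraries.

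Among genes with at least 1 FPKM in the higher group and no overlap between groups, the 5 highest fold changes were those of Hsd3b5, Chac1, Ptgds, Obox8 and Hcn3. Hsd3b5 (ENSMUSG00000038092, chromosome 3, 98618634 to 98630252), which encodes a steroid dehydrogenase found mainly in male mouse liver, stood at 0.0933 ± 0.110 FPKM in WT and 4.00 ± 2.45 in KO (SD, n = 3 each), a log2 fold change of 5.40 ± 0.85 (SE, edgeR adjusted p = 0.00238). Without WT replicate 3 the log2 fold change was 6.93 for Hsd3b5 and 3.69 for Obox8. Ptgds, which encodes a prostaglandin D synthase, had a log2 fold change of 3.23 ± 0.79 (SE, edgeR adjusted p = 0.00775), Obox8, an oocyte homeobox family gene, one of 2.98 ± 0.77 (SE, edgeR adjusted p = 0.00842), and Hcn3, an ion channel gene, one of 2.96 ± 0.52 (SE, edgeR adjusted p = 0.00290). Hcn3 and Pklr overlap by 711 bases on opposite strands, so with counting not stated to use strand their reads cannot be told apart there.

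The 5 lowest were Cidec, Mmp7, Cldn4, Cntnap1 and Cyp3a44. Mmp7 (ENSMUSG00000018623, chromosome 9, 7692090 to 7699585), which encodes the protease matrilysin, stood at 5.78 ± 6.85 FPKM in WT and 0.200 ± 0.0173 in KO (SD, n = 3 each), a log2 fold change of -4.80 ± 0.92 (SE, edgeR adjusted p = 0.00367). Cldn4, a tight junction gene, had a log2 fold change of -4.34 ± 1.17 (SE, edgeR adjusted p = 0.00931), Cntnap1 one of -4.26 ± 0.61 (SE, edgeR adjusted p = 0.00228), and Cyp3a44, a cytochrome P450 gene, one of -3.64 ± 0.96 (SE, edgeR adjusted p = 0.00899). WT replicate 3 carried part of 3 of these: without it the log2 fold changes were -3.13 for Mmp7, -2.16 for Cldn4 and -2.02 for Cyp3a44. That of Cntnap1 was -5.15 without KO replicate 1. Reads of Hsd3b5, Cyp3a44, Obox8 and Mt2 can be shared with close paralogs, and 15 of the 32 genes chosen by the rule overlap another annotated gene, so these levels are less certain.

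**Figure D3:**
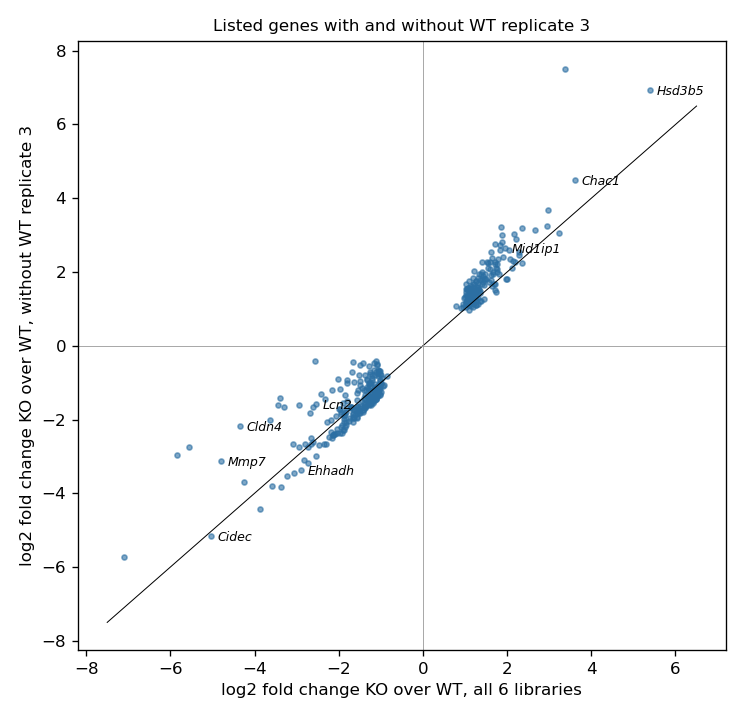
Log2 fold change of KO over WT for the 389 listed genes from all 6 libraries (x axis) and without WT replicate 3 (y axis), with each point a gene and the line marking equal values. No gene changed direction, which the selection on this comparison made likely. Genes such as Mmp7 (-4.80 and -3.13) and Cldn4 (-4.34 and -2.16) lay nearer 0 without that library.

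Other gene groups had few listed members, and none of them passed the one-sided exact hypergeometric test after adjustment. Some had more listed members than expected, such as 3 against 0.50 in the liver cancer and fetal group. Others were near it, such as 1 against 0.86 in the hepatocyte group. In the group of male and female biased liver genes, Hsd3b5, Mup21 and A1bg were higher in KO and Cyp3a44 was lower (4 of 45; adjusted p = 0.0731). The sex-linked members Xist, Ddx3y, Kdm5d, Eif2s3y and Uty of this group were not listed. If they were among the genes the authors tested, this argues against groups wholly of different sex. The labels do not give the sex of the mice, so a difference in sex between single samples is not excluded for these genes. Gpc3, Ly6d and Igdcc4 of the liver cancer and fetal group were lower in KO (3 of 21; adjusted p = 0.0517). Nr4a1, Hspb1 and Btg2 of the immediate early group were lower (3 of 24; adjusted p = 0.0679). Of the p53 and DNA damage group, Cdkn1a and Btg2 were lower and Gadd45a was higher (3 of 31; adjusted p = 0.105). Of the xenobiotic group, Cyp3a44 and Por were lower and Cyp2c54 was higher (3 of 44; adjusted p = 0.216). Both Nr1d1 and Ciart of the circadian group (2 of 19; adjusted p = 0.196) and both Mat1a and Mthfd1l of the one carbon and methionine group (2 of 25; adjusted p = 0.276) were lower. Rsad2 was lower and Gbp6 higher in the interferon group (2 of 46; adjusted p = 0.591). A single member was listed in the dendritic cell group (Ly6d, lower; 1 of 12), the cholangiocyte and ductular group (Cldn4, lower; 1 of 19), the hepatocyte group (Asl, lower; 1 of 36) and the adipocyte group (Cidec, lower; 1 of 9). The same held for the MYC and ribosome biogenesis group (Ldha, lower; 1 of 33) and the NRF2 and glutathione group (Osgin1, higher; 1 of 33). Several of these calls were lost when 1 library was left out, which also leaves fewer samples for the test. Asl, at a log2 fold change of -1.24 with all libraries, was -1.23, -1.23 and -1.24 without KO replicates 1, 2 and 3. It was -0.71 without WT replicate 2. Both one carbon genes failed without any 1 KO replicate, and 1 of them passed without WT replicate 2. Neither interferon gene passed without KO replicate 1 or 2, and 1 passed without KO replicate 3, WT replicate 2 or WT replicate 3. Asl did not pass without WT replicate 2 or any 1 KO replicate, Ldha without WT replicate 1, KO replicate 2 or KO replicate 3, and Osgin1 without KO replicate 2. In the circadian group 1 gene passed without WT replicate 1, KO replicate 1 or KO replicate 3. In the p53 group 1 gene passed without WT replicate 2 or KO replicate 2, and 2 without WT replicate 1, KO replicate 1 or KO replicate 3. In each of 3 groups 2 of 3 genes passed without certain libraries, namely KO replicate 2 or 3 for the immediate early group, these or WT replicate 1 for the liver cancer group, and KO replicate 1 or 3 for the xenobiotic group. No member was listed of the groups for T and NK cells, B and plasma cells, endothelium, erythroid cells, pancreas and gut, skeletal muscle, proliferation, other USP28 substrates, oxidative phosphorylation and the mitochondrial genome. A gene with no row was not tested here, and its level is not known to be unchanged. In every group the count of members that passed was equal when adjusted over the list alone.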

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

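Adjustment over the 16198 genes of the authors' test, with edgeR or DESeq2, was chosen after the data were seen, as were the membership test of the lists and the list medians without WT replicate 3. No listed gene changed direction when a library was left out, which the 363 genes without overlap between groups could hardly do. Under the other scalings none could, given the selection on fold change. With limma, median centring, TMM, DESeq2 at the recovered depth and a minimum absolute log2 fold change of 1, between 329 and 388 of the 389 genes passed, against 388. The 2 filters tested fewer genes: 318 of 320 passed at a mean FPKM of at least 1, and 377 of 379 with filterByExpr. Relative log expression factors gave 236 genes (156 higher, 80 lower) and DESeq2's own factors 239 (156 higher, 83 lower). Both scale each library by the median, over the listed genes, of its ratio to a mean library. They raised the fold changes of KO over WT by a median of 0.65 on the log2 scale, and 233 of the 389 genes stayed lower in KO. Median centring raised them by 0.33 and TMM by 0.29. Adjusted over 22028 protein-coding genes, 5 genes passed (0 higher, 5 lower), and over 16198 genes also 5 (0 higher, 5 lower), with genes without a row entered as unchanged. At an unadjusted p under 0.05, edgeR gave 388 genes, 155 of them higher. DESeq2's p-values over 16198 genes gave 153 (50 higher, 103 lower), and the cause of the difference between the tools was not tested. In both edgeR adjustments 3 of the 32 named genes passed (Cidec, Mt2 and Il1rn), and 24 with DESeq2. Leaving out each library in turn gave 278 to 372 genes, with 99 to 156 higher and 176 to 219 lower; the lowest total and the lowest number higher came without KO replicate 2. Cldn4 did not pass with limma at a pseudocount of 1 (log2 fold change -0.85), nor Lgals3 with relative log expression factors or DESeq2's own factors (-1.07 in both). The number of lists past the direction test was 3 in every setting, but that test uses only directions, which did not change. DESeq2 gave no adjusted p for 1 gene. With replicate number as a block, 382 genes passed (155 higher, 227 lower) and no named gene was lost. Same-numbered samples did not deviate together (correlations 0.05, 0.08 and -0.03 over the listed genes), and not every sample correlated best with its own number. The labels do not say whether the numbers pair the samples. With 3 samples per group and genes selected on this comparison, these correlations cannot decide it. In counts simulated at the depth and spread of these libraries, edgeR called 30 of 100 genes given a log2 change of 1. camera and fry were not run.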

Other observations

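The gene groups and tests in this part were chosen after the values were seen, except the test of the median share of sequence that zinc finger genes have in common with other genes. Several single genes outside the lists differed. Inhba, which encodes an activin subunit, had a log2 fold change of 2.27 ± 0.40 (SE, edgeR adjusted p = 0.00290) from counts, whereas its mean FPKM of 0.567 ± 0.172 in WT and 1.74 ± 0.584 in KO (SD, n = 3 each) gave a log2 ratio of 1.62. Inhbb (-1.81 ± 0.39, SE, edgeR adjusted p = 0.00543) and Inhbe (-1.40 ± 0.38, SE, edgeR adjusted p = 0.00931), which encode other subunits, were lower in KO. So was Fst, which encodes the activin-binding protein follistatin (-1.88 ± 0.52, SE, edgeR adjusted p = 0.0103). Nodal, which encodes a related ligand, was also lower (-3.36 ± 1.05, SE, edgeR adjusted p = 0.0137) at 0 to 22 counts per library, and did not pass without WT replicate 1 (-2.90, edgeR adjusted p = 0.0617). The KEGG pathway of TGF-beta signaling that holds these genes had 2 listed genes higher and 5 lower, which did not pass the two-sided Fisher's exact test of direction (adjusted p = 0.873). Among secreted regulators of lipid metabolism, Angptl8 was higher in KO (log2 fold change 1.32 ± 0.36, SE, edgeR adjusted p = 0.00931). Apoa4, an apolipoprotein gene, went from 4230 ± 1262 FPKM in WT to 1074 ± 423 in KO (SD, n = 3 each, log2 fold change -1.98 ± 0.45, SE, edgeR adjusted p = 0.00632). Slc2a5, which encodes a fructose transporter, had a log2 fold change of 2.01 ± 0.38 (SE, edgeR adjusted p = 0.00356).

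Beside Hsd3b5, the steroid enzyme genes Hsd3b2 (1.61 ± 0.34, SE), Hsd3b3 (1.54 ± 0.41, SE) and Akr1c14 (1.77 ± 0.39, SE) were higher (edgeR adjusted p = 0.00462, 0.00922 and 0.00583), as was Serpina6, which encodes the corticosteroid-binding globulin (1.91 ± 0.40, SE, edgeR adjusted p = 0.00462). The Hsd3b genes are close paralogs whose reads can be shared. By the authors' deposited KEGG annotation, steroid hormone biosynthesis had 7 listed genes higher and 1 lower, and PPAR signaling had 1 higher and 15 lower. Neither passed the two-sided Fisher's exact test of direction over the 79 pathways with at least 5 listed genes (p = 0.00810 and 0.00353, adjusted p = 0.236 for both).

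WT replicate 3 stood apart from the other WT libraries. Between genes, its log2 difference from them had an SD of 1.08, against 0.61 and 0.74 for WT replicates 1 and 2 and 0.39 to 0.46 for the KO libraries, and without it 17 calls were lost and 57 fold changes moved by over 1.5 times. Its depth differed by only -0.0891% from WT replicate 1, which argues against depth as the cause. A wrong label stays open: 65.8% of listed genes lay nearer the other WT libraries and Cidec had 2315 counts against 83 to 99 in KO, but the genes were selected with this library counted as WT and Usp28 has no row. The tables argue against dilution of hepatocyte RNA as the whole cause, since its oxidation genes were lower than in the other WT libraries (median -1.21, quartiles -1.52 to -1.06) but its droplet genes were not (-0.10, quartiles -0.48 to 0.31), a gap of 1.11, and its lipogenic genes were higher (median 1.18, lower quartile 0.75). Its cholesterol genes were also higher, by a median of 1.52 (quartiles 1.275 to 1.881), as were its stress genes, by 1.32 (quartiles 1.209 to 1.468). Its macrophage markers were higher by a median of 1.63 (quartiles 0.69 to 2.09), so more macrophage RNA stays open. A difference in disease stage or feeding of that sample stays open too, and no biological explanation was tested.

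Of the listed genes, 8 of 11 in the lipogenesis group were higher in KO, a split that did not pass its test of direction (adjusted p = 0.0702), and all 19 in the oxidation group were lower. Scaling moves all genes of a library alike, which argues against it for the direction of the oxidation group, whose split differed from that of the other listed genes (two-sided Fisher's exact test, adjusted p = 0.000457, genes of a list not being independent). The size of its difference does depend on scaling. Its median log2 fold change was -1.52, and relative log expression factors raised fold changes by a median of 0.65. They left 80 of the 233 lower listed genes past the threshold, and those of the oxidation group were not counted apart. For the lipogenesis group the test of direction does not decide. All 156 genes higher in KO, its 8 among them, passed with median centring, TMM, relative log expression factors and DESeq2's own factors. These scalings, set on the selected genes, raised the fold changes of KO over WT by a median of 0.29 to 0.65 on the log2 scale. Passing was therefore favoured for genes higher in KO, and it does not decide whether scaling accounts for the higher genes of the group. A candidate explanation beside genotype is a different feeding state at collection, since fed liver has more lipogenic and fasted liver more oxidation transcripts. Within WT, replicate 3 had lipogenic genes higher by a median of 1.18 than the other WT libraries and oxidation genes lower, so the lists also moved together between samples of 1 genotype. Food intake is not in the labels, and genotype and feeding cannot be told apart here.

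All 9 listed genes named Zfp, which encode zinc finger proteins, were higher in KO (log2 fold changes from 1.01 to 1.70), at least 4 of them passed whichever library was left out, and all 9 listed predicted genes named Gm were higher too, so the pattern is not particular to zinc finger genes. Low counts alone do not account for it, since of 154 other listed genes with mean counts in the same range 65 (42.2%) were higher, nor does a block of sequence linked to the Usp28 locus on chromosome 9, where 0 of the 9 genes lie. Reads shared between paralogs stay open for most of them, with a median of 11.9% of their 50-base windows also found in other genes, from 3.05% in Zfp160 to 89.9% in Zfp968-ps where any was shared. For the 2 zinc finger genes without shared windows, Zfp276 and Zfp383, exact sharing is excluded. An effect of genotype may also account for the pattern, which was noticed in these data and not tested on others.

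Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many genes as the real one, namely the real split itself, with 388. The highest of the others gave 0 genes by edgeR at an adjusted p under 0.05, and 19 at an unadjusted p under 0.05. With 10 splits the share cannot go below 0.1, and the listed genes were selected on the real split.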
